A study of Vaccinium corymbosum with 9 samples.

How the data were processed

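RNA-seq of blueberry fruit (Vaccinium corymbosum, 'Bluecrop') was deposited for 9 libraries, 3 at each of the early green, color break and mature stages, made from total RNA extracted with TRIzol and sequenced on the Illumina NovaSeq platform. The labels describe the replicates as independent biological replicates. The library protocol text speaks of a Populus hybrid under alkaline stress, whereas the organism field and the gene names are those of blueberry. The submitters name fastp, HISAT2, StringTie and DESeq2 as processing tools, and their versions, settings and the genome build are not given in the sources used here.

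The deposited table holds 93716 genes on 1326 scaffolds with FPKM and estimated counts for each library. FPKM values were made by the authors from the length of each transcript model and a library total, and the estimated counts summed to 52919289 to 67604266 per library. The estimated counts are whole numbers as deposited, equal to FPKM times length times 1 constant per library, rounded up, and so come from fractional coverage estimates. They were used as deposited as input to the count models, which scale between libraries with TMM. Samples were grouped by stage as labelled.

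Genes with an FPKM of at least 1 in at least 3 libraries were tested, 48073 in all, of which 78.6% carry a GO term, a KEGG ortholog or a protein name. edgeR 4.0.16 in R 4.3.3 was used with TMM scaling, robust quasi-likelihood fits and stage as the only term, for color break against green, mature against color break and mature against green, and for an F test over the stages. The test named beforehand was limma on log2(FPKM + 1) for a table without counts and edgeR where whole counts are given, and edgeR applied. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 change of at least 1, and the F test used the adjusted p alone. TMM factors were 1.13 to 1.15 in green, 0.927 to 0.932 in color break and 0.937 to 0.945 in mature libraries, so log2 changes carry this scaling and FPKM means do not. A gene without counts in a stage was set to a floor of 3 counts per library for its lower bound of fold.

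Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 on log2 CPM (prior count 1), with an estimated correlation as alternative and with fry, for lists of at least 5 tested genes. Adjustment ran over the lists of a comparison. Before the data were examined 21 lists were fixed, and 12 lists built on GO terms were added after the annotation was seen and adjusted on their own. Terms of GO with 20 to 500 tested genes were tested in the same way. Named genes followed a rule fixed before the data were examined. From each list it takes the called gene with the largest rise and that with the largest fall whose libraries do not overlap between the stages, where chance alone gives 10% for 3 against 3. Outside the lists it takes the 5 largest rises and 5 largest falls with at least 10 FPKM in the higher stage and a named protein. From 10 families it takes the most highly expressed gene, by mean FPKM over the 9 libraries. Every gene named as rising or falling has all 3 libraries of 1 stage above all 3 of the other. Genes outside the rule are named as chosen after their values were seen.

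The models were tested on simulated data of 48073 genes. At color break 50 genes were changed at each of the folds 1.5, 2, 4 and 8, with as many raised as lowered, and 47873 were unchanged. Far more genes changed in the data, so the rates below need not hold there. For color break against green, 36% of genes changed 2-fold and 92% of those changed 4-fold were called, for mature against color break 44% and 94%, and 0.0125% of unchanged genes were called in each. Alternatives within edgeR were no filter, a mean FPKM of at least 5, median-of-ratios scaling, a replicate block, only the 2 stages of a comparison, each library left out, copies with the same description summed, and no fold threshold. A change of filter or of summing also recomputes the TMM factors. DESeq2 1.42.0 was used as another count model. Pseudocounts of 0.1 and 0.5, TPM, quantile scaling, and no trend or robust fit were planned for FPKM and run in limma without TMM, so each differs from the edgeR result in more than 1 choice and is set against limma on log2(FPKM + 1). For lists, camera on quantile scaled FPKM or on FPKM with a pseudocount of 0.1 also replaces TMM-scaled CPM. Library-size-only scaling, a mean FPKM of at least 5 and at least 5 FPKM in the highest of the stages compared, both with the library sizes and TMM factors of the main fit, edgeR without robust fit, exclusion of seed storage genes, and limma on log2(FPKM + 1) were added after the data were seen. Raw reads were not analysed here.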

Results

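RNA from fruit of the blueberry cultivar 'Bluecrop' (Vaccinium corymbosum) was sequenced at 3 natural developmental stages, early green, color break and mature. The labels describe 3 independent biological replicates per stage, so 9 libraries were compared, and they place the formation of the fruit's cuticular wax, the whitish bloom on the skin, at the centre of the study. The deposited estimated counts summed to 56014561, 52919289 and 53275930 in green replicates 1 to 3, to 53154398, 64267622 and 67604266 in color break replicates 1 to 3, and to 55810987, 56402366 and 53708145 in mature replicates 1 to 3. A count of 0 in a library allows up to 3 counts, or 0.0444 to 0.0567 CPM (counts scaled to the library total), and this floor covers counting error only. Of 93716 annotated genes, 48073 reached an FPKM of at least 1 in at least 3 libraries and were tested. FPKM values below are means ± SD over the libraries of a stage (n = 3), and log2 changes are edgeR estimates ± SE. A single value in parentheses after the counts of a list is its camera adjusted p. Positions are scaffold coordinates from the deposited table, whose genome build is not given in the sources used here. The genome holds several near-identical copies of many genes, so the division of reads between copies is uncertain.

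The green libraries stood far from the other stages. The first principal component held 73.7% of the variance and parted green from color break and mature fruit, and PC2 held 7.18%. Correlations of log2 CPM across genes lay between 0.734 and 0.786 for green against color break libraries, and between 0.939 and 0.954 for color break against mature libraries. Color break replicate 3 stood apart from the other color break libraries, at 67.6 on PC1 against 125 and 113 for replicates 1 and 2. Within color break the correlations ranged from 0.939 to 0.969, within green from 0.971 to 0.971 and within mature from 0.955 to 0.964. Across the 3 stages, 28360 genes (59.0%) changed in the edgeR F test.

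**Figure D1:**
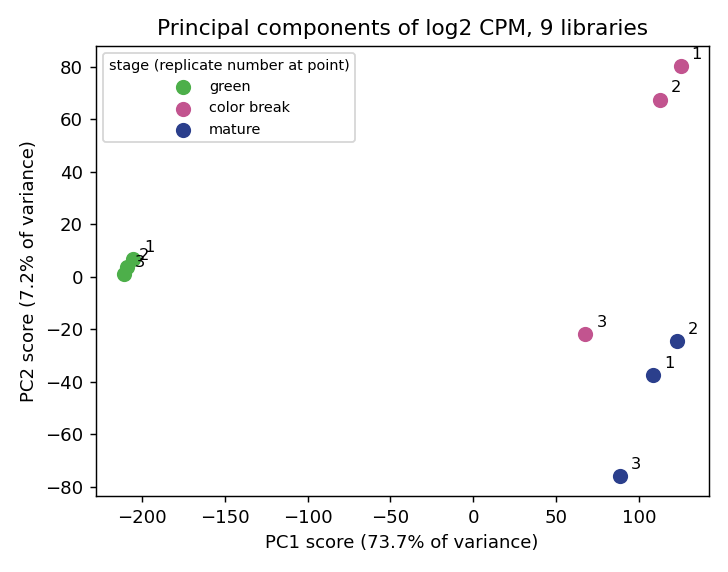
Principal components of log2 CPM over the tested genes, with PC1 on the x axis (73.7% of the variance) and PC2 on the y axis (7.18%), 1 point per library, colored by stage and marked with its replicate number. The green libraries sit at -205 to -211 on PC1, and color break replicate 3 sits at 67.6.

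The comparison of color break with early green fruit asks which genes change as the berry starts to color. Of 130 genes of the flavonoid and anthocyanin pathway, which makes the blue and red skin pigments, 91 rose, 14 fell and 25 were not called (camera adjusted p = 5.1e-23, not called with an estimated correlation at adjusted p = 0.0883). Chalcone synthase, the entry enzyme of flavonoid synthesis, went from a summed 32.7 ± 0.729 FPKM over its 12 genes in green fruit to 2625 ± 226 at color break. Of 45 photosynthesis genes 19 fell and 26 were not called, and of 45 genes of triterpenoid synthesis, the route to cyclic wax terpenoids, 26 fell and 7 rose, and both lists lost their camera call with an estimated correlation (adjusted p = 0.0883 for each). The wax elongation genes moved in both directions: of 39 genes for 3-ketoacyl-CoA synthase (KCS), which sets the chain length of wax precursors, 4 rose and 19 fell. Over all genes tested 10979 (22.8%) were called, of which 4274 rose and 6705 fell (edgeR), but among genes with at least 5 FPKM in the higher of the 2 stages, a filter chosen after the data were seen, 2746 rose and 2339 fell at the same scaling.

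The flavonoid and anthocyanin list had a median log2 change of 3.97, but its families differed: of 17 anthocyanidin glycosyltransferase genes 7 rose and 6 fell, with a median of -0.92. All 12 chalcone synthase genes rose, as did all 4 dihydroflavonol reductase (DFR) genes and 3 of 4 anthocyanidin synthase (ANS) genes. The chalcone synthase gene VaccDscaff4-processed-gene-104.3 (scaffold 4, 10454644 to 10457528, 2 exons) rose from 1.59 ± 0.264 to 796 ± 93.2 FPKM, a log2 change of 9.23 ± 0.19 (adjusted p = 2.5e-09). The ANS gene VaccDscaff43-augustus-gene-236.29 (scaffold 43, 23629220 to 23633350, 3 exons) rose from 4.01 ± 0.410 to 912 ± 61.7 FPKM (log2 change 8.10 ± 0.13, adjusted p = 3.1e-10). The DFR gene VaccDscaff42-processed-gene-96.9 (scaffold 42, 9604507 to 9608970, 7 exons) rose by 3.63 ± 0.09 on the log2 scale (adjusted p = 2.0e-09). A phenylalanine ammonia-lyase gene, VaccDscaff10-augustus-gene-222.30, had no counts in the green libraries and was at least 136-fold higher at color break. In the same way a flavonoid 3',5'-hydroxylase gene, VaccDscaff29-augustus-gene-305.28, whose enzyme opens the route to blue delphinidin pigments, was at least 119-fold higher. Outside the lists, genes named MYB1 and MYB9 rose too. These are names from a family of which some members control anthocyanin genes in many plants, and whether these genes do so was not tested. MYB1 gene VaccDscaff1486-snap-gene-0.3 (scaffold 1486, 3155 to 6167, 3 exons) went from 0.0554 ± 0.0480 to 135 ± 17.3 FPKM (11.31 ± 0.35, adjusted p = 4.0e-08), and the MYB9 gene VaccDscaff6-snap-gene-261.32 from 0.245 ± 0.0862 to 20.5 ± 2.89 FPKM (6.63 ± 0.23).

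The GO-based anthocyanin list moved the same way, with 41 of 80 genes rising and 9 falling (camera adjusted p = 4.2e-09, and adjusted p = 0.138 with an estimated correlation). The proanthocyanidin list, on condensed tannins, had 4 rises and 4 falls among 10 genes (adjusted p = 0.791), with the leucoanthocyanidin reductase gene VaccDscaff28-augustus-gene-232.26 rising (log2 change 2.92 ± 0.26) and VaccDscaff36-augustus-gene-103.16 falling (log2 change -4.05 ± 0.59). In the GO-based proanthocyanidin list 13 of 24 rose and 3 fell (adjusted p = 7.8e-04, and adjusted p = 0.0807 with an estimated correlation). The lignin pathway list was chosen beforehand to mark stone cells and vessels, whose share of the fruit was not measured. It moved with the pigments: 21 of its 35 genes rose and none fell (adjusted p = 3.8e-11, and adjusted p = 0.0883 with an estimated correlation). Its caffeoyl-CoA O-methyltransferase gene VaccDscaff42-processed-gene-262.6 went from 4.85 ± 0.350 to 326 ± 26 FPKM (6.34 ± 0.12, adjusted p = 3.8e-10). That list took 0.0770% ± 0.00280 of the counts in green fruit and 0.532% ± 0.0318 at color break, shares 2 genes with the proanthocyanidin list, and has 10 genes over 10 FPKM in green fruit.

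**Figure D2:**
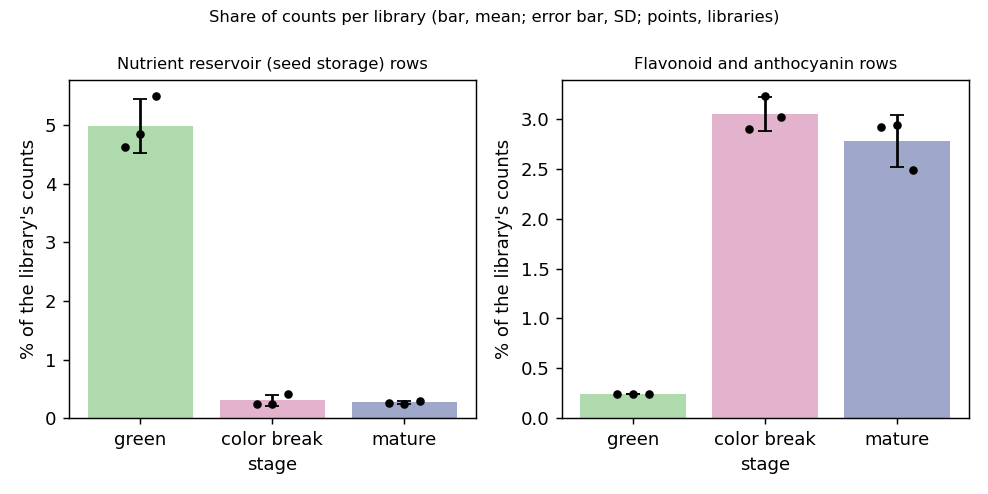
Share of each library's counts, in percent, taken by the nutrient reservoir (seed storage) genes and by the flavonoid and anthocyanin genes at each stage; bars are means, error bars SD and points the 3 libraries. The storage genes went from 4.99% in green fruit to 0.304% at color break, and the pigment genes from 0.243% to 3.05%.

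In the wax elongation list, 5 of 64 genes rose and 19 fell from green to color break (median -0.20, camera adjusted p = 0.124). All of its falls and 4 of its rises lay in the KCS family, whereas none of 11 ketoacyl-CoA reductase and 6 hydroxyacyl-CoA dehydratase genes was called. The summed level of the KCS genes was 397 ± 11.1 FPKM in green fruit and 391 ± 50.2 at color break. The most highly expressed KCS gene, VaccDscaff24-augustus-gene-329.18 (scaffold 24, 32890614 to 32896905, 3 exons), rose from 48.2 ± 2.11 to 121 ± 19.6 FPKM (1.60 ± 0.13, adjusted p = 8.8e-06), a call that ended when copies with the same description were summed. The other rising KCS genes were almost silent in green fruit. VaccDscaff20-augustus-gene-127.40 (scaffold 20, 12748972 to 12751339, 3 exons) went from 0.0373 ± 0.0472 to 19.1 ± 3.17 FPKM (9.14 ± 0.45, adjusted p = 7.7e-07), and VaccDscaff28-augustus-gene-219.27 (scaffold 28, 21928597 to 21931240, 3 exons) and VaccDscaff19-snap-gene-130.30, both chosen after their values were seen, rose by 7.51 ± 0.29 and 7.47 ± 0.34 on the log2 scale. Beside the genes on scaffolds 20 and 28 lie VaccDscaff20-processed-gene-127.33 and VaccDscaff28-processed-gene-219.2, which carry the same description and had no counts in green fruit. Neither has a KEGG ortholog, so they are not counted among the KCS genes. They were at least 168-fold and at least 164-fold higher at color break, and the gene on scaffold 28 was chosen after its values were seen. Among the falling KCS genes, VaccDscaff2-augustus-gene-426.23 went from 3.63 ± 0.895 to 0.0822 ± 0.0768 FPKM (log2 change -5.06 ± 0.84).

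The single tested gene for CER1, the enzyme that forms wax alkanes, was VaccDscaff37-augustus-gene-293.17 (scaffold 37, 29284952 to 29293714, 11 exons). It rose from 56.2 ± 2.93 to 102 ± 5.46 FPKM (1.14 ± 0.08, adjusted p = 1.2e-06), close to the fold threshold, and was no longer called in 8 of the alternatives, among them library-size-only scaling and limma on log2(FPKM + 1). Of 3 genes for fatty acyl-CoA reductase, which makes wax alcohols, 1 fell, VaccDscaff47-snap-gene-54.13 (log2 change -1.90 ± 0.38, not called with quantile scaling, copies summed or limma on log2(FPKM + 1)), and the most highly expressed, VaccDscaff46-augustus-gene-104.22, had 5.85 ± 0.233 and 3.54 ± 1.47 FPKM (adjusted p = 0.22). The wax modification list so had 1 rise and 1 fall among 4 genes. For CER3 and midchain alkane hydroxylase the annotation text matched 0 genes, which leaves their expression open, and the 1 gene matched for wax ester synthase did not pass the expression filter. Among 12 cutin genes, all for glycerol-3-phosphate acyltransferase (GPAT), which builds the cutin polyester, 3 rose and 6 fell (median -1.69, adjusted p = 0.791, with fry pointing up and camera down). The GPAT gene VaccDscaff27-augustus-gene-30.24 (scaffold 27, 3001167 to 3005793, 2 exons) rose from 1.65 ± 0.0669 to 3.91 ± 0.739 FPKM (1.52 ± 0.16, adjusted p = 3.0e-05), a call lost with limma on log2(FPKM + 1). The 13 genes matched for CYP86A and CYP77A hydroxylases, 3 for a GPI-anchored lipid transfer protein and 4 for the regulators CER7, CER9, DEWAX and HDG1 did not pass the filter, and for the other families of the cutin, wax export and cuticle regulator lists the annotation matched 0 genes. In the GO-based lists, 10 of 67 wax biosynthesis genes rose and 26 fell (adjusted p = 0.179), 4 of 28 cutin genes rose and 12 fell (0.168), 2 of 29 cuticle development genes rose and 2 fell (0.896), and 3 of 13 cuticle hydrocarbon genes rose and 2 fell (0.902). For suberin 2 of 21 genes rose and 4 fell (0.713), and for very-long-chain fatty acids 0 of 45 rose and 4 fell (0.343).

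Of 45 triterpenoid genes, 7 rose and 26 fell (median -1.56, camera adjusted p = 1.7e-04, and adjusted p = 0.0883 with an estimated correlation). Oxidosqualene cyclases, which fold squalene oxide into triterpene skeletons, had 13 falls and 4 rises among 19 genes, and squalene synthases and epoxidases 7 falls and 2 rises among 13. The most highly expressed cyclase, VaccDscaff20-snap-gene-210.31 (dammarenediol II synthase-like, scaffold 20, 21035549 to 21047649, 18 exons), went from 21.5 ± 0.969 to 1.91 ± 0.685 FPKM (log2 change -3.22 ± 0.33, adjusted p = 6.4e-05). The cyclase gene VaccDscaff23-snap-gene-88.33 had 2.08 ± 0.592 FPKM in green fruit and no counts at color break, at least 122-fold lower. In the GO-based triterpenoid list 8 of 34 rose and 13 fell (adjusted p = 0.179). The share of the counts moved in opposite directions in the 2 lists. Over all annotated genes, it rose from 0.0701% ± 0.00239 to 0.125% ± 0.00144 in the GO-based list. In the fixed list it fell from 0.0807% ± 0.00246 to 0.0476% ± 0.000556.

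No photosynthesis gene rose and 19 of 45 fell (median -0.83, adjusted p = 2.9e-10, and adjusted p = 0.0883 with an estimated correlation). The photosystem I gene VaccDscaff46-processed-gene-156.1 went from 48.6 ± 1.68 to 7.59 ± 0.557 FPKM (log2 change -2.41 ± 0.08). In the GO-based light harvesting list 34 of 49 genes fell and 4 rose (adjusted p = 1.3e-06, and adjusted p = 0.163 with an estimated correlation). Of 16 chlorophyll breakdown genes 7 fell and 0 rose (adjusted p = 0.911). Seed storage genes had the lowest median of the lists tested: in the GO-based nutrient reservoir list 62 of 82 fell and 4 rose, with a median of -6.63, or -6.59 with genes at 0 set to their bound (adjusted p = 1.0e-13, and adjusted p = 0.149 with an estimated correlation). The storage gene VaccDscaff11-snap-gene-368.41 had 52.2 ± 6.05 FPKM in green fruit and was at least 3534-fold lower at color break. These genes took 4.99% ± 0.458 of the counts in green fruit and 0.304% ± 0.0988 at color break, with 0.418% in color break replicate 3. The fixed seed tissue list had 9 rises and 6 falls among 21 genes (adjusted p = 0.915). Outside the lists AGL11, a MADS-box factor of ovule and seed identity (VaccDscaff2-augustus-gene-218.35), went from 26.2 ± 5.15 to 0.602 ± 0.639 FPKM (log2 change -5.10 ± 0.84). Among the same largest falls was receptor-like protein 7 gene VaccDscaff8-processed-gene-60.6, from 11.9 ± 1.90 to 0.0803 ± 0.0458 FPKM.

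Genes of organic acid metabolism rose more often than they fell, 32 against 4 of 99 (adjusted p = 2.7e-04, and adjusted p = 0.0883 with an estimated correlation). ATP citrate lyase, which makes cytosolic acetyl-CoA from citrate, accounted for 17 of the rises among its 20 genes, with VaccDscaff35-snap-gene-201.18 going from 1.63 ± 0.322 to 39.1 ± 4.16 FPKM (4.85 ± 0.15). In the sugar list 10 of 46 rose and 6 fell (adjusted p = 0.0490), with adjusted p = 0.109 with an estimated correlation. That call was lost without green replicate 2 or 3, color break replicate 1 or 2, or mature replicate 1 or 2, at adjusted p values of 0.0547 to 0.0611, over a range of 0.0189 to 0.709 for all alternatives. For abscisic acid, a ripening hormone, 14 of 30 genes rose and 5 fell (adjusted p = 0.142), including 8 of 11 genes of its synthesis enzyme 9-cis-epoxycarotenoid dioxygenase, of which 3 fell, and all 4 genes of its breakdown enzyme ABA 8'-hydroxylase, such as VaccDscaff14-snap-gene-19.34 (0.0702 ± 0.0675 to 11.5 ± 2.52 FPKM). For ethylene 8 of 31 rose and 6 fell (0.190). Cell wall softening genes moved both ways, 35 rising and 59 falling of 201 (0.734), with 21 rises among 66 polygalacturonase and pectate lyase genes and 40 falls among 119 genes for pectinesterase, beta-galactosidase and endoglucanase.

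Of 9 cell cycle genes 5 fell and 0 rose (adjusted p = 0.0233, and adjusted p = 0.109 with an estimated correlation), whereas in the GO-based mitotic list 23 of 182 rose and 12 fell (0.0696). For defence, 26 of 49 genes rose and 5 fell (adjusted p = 0.00376, and adjusted p = 0.123 with an estimated correlation). The defence genes took 0.564% and 0.591% of the counts in color break replicates 1 and 2 and 1.17% in replicate 3. Of 85 heat stress genes 5 rose and 11 fell (0.306), and of 45 ribosomal protein genes, kept as a reference, 0 rose and 1 fell (0.741). Median and mean log2 change differed in sign for chlorophyll breakdown (0.16 and -0.61), sugar (0.30 and -0.57) and ribosomal proteins (0.07 and -0.07), and the seed tissue median was -0.44 where camera pointed up. In fry, which weighs the genes of a list without comparing them with others, the proanthocyanidin list and the GO-based wax, cuticle development and cuticle hydrocarbon lists pointed up where their medians (-0.49, -0.45, -0.02 and -0.25) and camera pointed down. Adjusted over the list alone, the counts of the fixed lists were the same except for 15 falls in the flavonoid, 8 in the seed tissue and 6 in the defence list. With copies summed the triterpenoid (adjusted p = 0.0662), organic acid (0.0712), sugar (0.105), defence (0.105) and cell cycle (0.225) calls ended, and the cell cycle call also with quantile scaling (0.173), a pseudocount of 0.1 (0.0686) and library size only (0.0577).

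**Figure D3:**
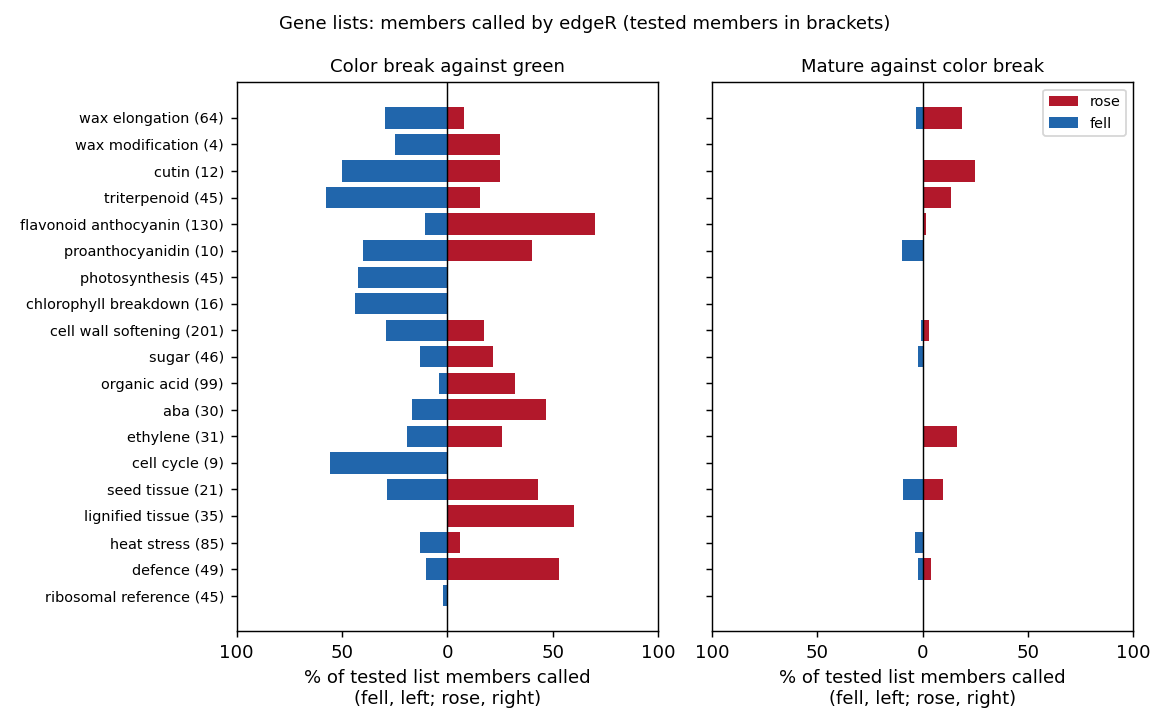
Percent of the tested genes of each of 19 gene lists that rose (right) or fell (left), for color break against green and for mature against color break fruit, with the number of genes tested beside each list. The flavonoid and anthocyanin list has 91 rises of 130 genes in the first comparison and 2 in the second.

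The comparison of mature with color break fruit asks what changes as colored berries ripen. Changes were fewer, and surface lipid genes were among them: 12 of 39 KCS genes rose and 2 fell, 3 of 12 GPAT genes rose, and 4 of 13 CYP716A oxidases, which make wax triterpenoid acids such as oleanolic and ursolic acid, rose with 0 falls. The summed KCS level went from 391 ± 50.2 to 531 ± 64.2 FPKM. Most of this gain lay in KCS genes not called at this step, as the called rises reached at most 6.91 FPKM in mature fruit. Some of these uncalled genes passed the adjusted p and missed only the fold threshold. Examples, chosen after their values were seen, are VaccDscaff19-augustus-gene-155.20 (35.8 and 65.7 FPKM, log2 change 0.86, edgeR adjusted p = 0.0060) and VaccDscaff15-augustus-gene-60.24 (30.6 and 54.9 FPKM, 0.83, 0.0043). No uncalled KCS gene lay lower past the adjusted p. Chalcone synthase genes summed to 2625 ± 226 and 2426 ± 310 FPKM. In all, 661 genes (1.37%) were called in edgeR, of which 367 rose and 294 fell. Falls outnumbered rises without a fold threshold (1322 rises and 1608 falls) and with a mean FPKM of at least 5 at the main scaling (93 and 99). In the other alternatives more genes rose than fell. The number of called genes moved to 1050 without color break replicate 3, 415 without mature replicate 3, 1036 with DESeq2, 346 with only these 2 stages in the fit, 246 in limma on log2(FPKM + 1) and 225 in limma with quantile scaling.

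Of 64 wax elongation genes 12 rose and 2 fell (median 0.25, camera adjusted p = 1.1e-05, and adjusted p = 0.0554 with an estimated correlation). The largest rise was in the KCS gene VaccDscaff794-augustus-gene-0.7 (scaffold 794, 16221 to 21532, 3 exons), which had 12.7 ± 0.433 FPKM in green fruit and went from 0.853 ± 0.302 at color break to 4.82 ± 0.416 in mature fruit (2.48 ± 0.21, adjusted p = 9.0e-04). VaccDscaff20-processed-gene-127.33, which lies beside a KCS gene but is not in this list, rose again. It went from 14.6 ± 1.71 to 34.4 ± 4.09 FPKM (1.21 ± 0.13, adjusted p = 0.0036), a call lost with copies summed. The most highly expressed KCS gene, VaccDscaff24-augustus-gene-329.18, had 141 ± 19.3 FPKM (0.20 ± 0.13, adjusted p = 0.41), and the CER1 gene 107 ± 9.42 FPKM (0.04 ± 0.07, adjusted p = 0.82). None of the 4 wax modification genes was called. In the GO-based wax biosynthesis list 5 of 67 rose and 0 fell (adjusted p = 0.00196, and adjusted p = 0.169 with an estimated correlation).

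Of 12 cutin genes 3 rose and 0 fell (median 0.16, adjusted p = 1.3e-04), a call that held with an estimated correlation (adjusted p = 0.0433). That correlation was negative (-0.0333), so it made no allowance for genes that move together. GPAT gene VaccDscaff27-augustus-gene-30.24 rose again, to 9.29 ± 1.39 FPKM (1.23 ± 0.15, adjusted p = 0.0031). In the GO-based cutin list 6 of 28 rose and 0 fell (median 0.57, adjusted p = 2.3e-09, and adjusted p = 0.00777 with an estimated correlation). Outside the lists the largest rises included the GDSL lipase gene VaccDscaff37-augustus-gene-13.28 (scaffold 37, 1354960 to 1367625, 6 exons), of a family that includes cutin synthases, from 5.45 ± 1.80 to 18.0 ± 2.13 FPKM (1.70 ± 0.24, adjusted p = 0.0080). The glycerol-3-phosphate dehydrogenase gene VaccDscaff18-augustus-gene-376.35, whose enzyme makes the glycerol backbone of lipids, rose from 4.26 ± 0.943 to 11.2 ± 1.06 FPKM (1.37 ± 0.16, adjusted p = 0.0024). For suberin 0 genes were called (adjusted p = 0.00423, and adjusted p = 0.0515 with an estimated correlation), for cuticle development 0 (0.0666), for cuticle hydrocarbons 0 (0.805), and for very-long-chain fatty acids 3 rose (0.419).

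Of 45 triterpenoid genes 6 rose and 0 fell (median 0.38, adjusted p = 1.3e-04, and adjusted p = 0.0857 with an estimated correlation). The CYP716A oxidase gene VaccDscaff10-augustus-gene-192.35 (scaffold 10, 19197215 to 19202225, 4 exons) went from 2.01 ± 0.238 FPKM in green fruit to 0.557 ± 0.194 at color break and 3.42 ± 0.770 in mature fruit, a log2 change of 2.58 ± 0.27 at this step (adjusted p = 0.0017). The dammarenediol II synthase-like gene had 2.88 ± 1.04 FPKM in mature fruit (0.57 ± 0.31, adjusted p = 0.34). In the GO-based triterpenoid list 1 of 34 rose (0.180).

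The GO-based light harvesting list lay down against other genes, although 4 of its 49 genes fell, 0 rose and 45 were not called (median -0.71, adjusted p = 1.4e-22), a call that held with an estimated correlation (adjusted p = 0.0203). The photosynthesis list had a median of -0.41 with 0 of 45 genes called (adjusted p = 9.2e-08, and adjusted p = 0.102 with an estimated correlation). In the flavonoid and anthocyanin list 2 genes rose and 0 fell, with a median of -0.16 (adjusted p = 0.00288, and adjusted p = 0.606 with an estimated correlation), and its call was lost without mature replicate 3, at adjusted p = 0.143 within a range of 2.5e-04 to 0.606. The GO-based anthocyanin list had 0 calls (0.0587). Of 10 proanthocyanidin genes 0 rose and 1 fell (median -0.41, adjusted p = 0.00766, and adjusted p = 0.102 with an estimated correlation), and the GO-based list had 1 rise and 1 fall (adjusted p = 0.00951, and adjusted p = 0.0561 with an estimated correlation). In the lignin pathway list 0 genes were called (median -0.24, adjusted p = 0.0349, and adjusted p = 0.498 with an estimated correlation), and its call was lost without color break replicate 1 (0.0581), color break replicate 2 (0.146) or mature replicate 3 (0.143), within a range of 0.0117 to 0.498.

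In the sugar list 0 genes rose and 1 fell, yet the list as a whole lay up against other genes (median 0.10, adjusted p = 4.4e-05), which held with an estimated correlation (adjusted p = 0.0395). For ethylene 5 of 31 genes rose and 0 fell (0.0703), and 4 of the rises were among 9 genes of ACC oxidase, which makes the hormone. The ACC oxidase gene VaccDscaff39-augustus-gene-284.28 rose from 2.00 ± 0.902 to 8.85 ± 3.11 FPKM (2.12 ± 0.37, adjusted p = 0.017), a call lost in the fit of only these 2 stages and with a replicate block. The late embryogenesis abundant protein gene VaccDscaff26-augustus-gene-358.26, of the seed tissue list, fell from 12.2 ± 1.74 to 4.12 ± 0.790 FPKM (log2 change -1.58 ± 0.15). That list had 2 rises and 2 falls (0.532), and the nutrient reservoir list 0 rises and 5 falls (median -0.32, or -0.22 with genes at 0 at their bound, 0.0666). For cell wall softening 6 rose and 2 fell (0.809), for organic acids 0 (0.480), for abscisic acid 0 (0.287), for chlorophyll breakdown 0 (0.650), for the cell cycle 0 (0.809), for the mitotic list 0 rose and 3 fell (0.461), for heat stress 0 rose and 3 fell (0.298), for defence 2 rose and 1 fell (0.809), and for ribosomal proteins 0 (0.319). Median and mean differed in sign for cell wall softening (-0.02 and 0.04), abscisic acid (0.12 and -0.07), ribosomal proteins (-0.04 and 0.02), and the GO-based cuticle hydrocarbon (0.01 and -0.05) and triterpenoid lists (0.10 and -0.04). Adjusted over the list alone, the fixed lists gave the same counts except 13 rises for wax elongation, 8 rises and 1 fall for triterpenoids, 6 rises for ethylene, 1 fall for photosynthesis, 3 falls for seed tissue and 3 for defence. With copies summed the triterpenoid (adjusted p = 0.370), flavonoid (0.370), proanthocyanidin (0.129) and lignin (0.401) calls ended, and with fry the flavonoid (0.277) and lignin (0.233) calls.

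Some KCS genes were called as falling to color break and rising after it, although the summed KCS level was 397 ± 11.1 FPKM in green fruit and 391 ± 50.2 at color break. Of the 39 KCS genes, 19 fell from green to color break, 12 rose from color break to mature, and 10 did both, against 5.85 for independent steps. These 10 had 0.183 to 0.937 FPKM at color break and share 5 descriptions, so near-identical copies are counted apart. Over all genes 197 fell and then rose, against 51.2, and 60 rose and then fell, against 26.1, while 53 rose at both steps, against 32.6, and 90 fell at both, against 41.01. A low value in the shared color break libraries enters both steps. With the fall and the rise measured on different color break libraries, in all 6 divisions, between 32 genes (12.8 expected) and 296 genes (79.0 expected) fell and then rose, 2.05-fold to 3.75-fold the number for independent steps. The KCS genes that did both then numbered 4 to 11, at 1.14-fold to 2.17-fold, with 1-sided Fisher p from 0.0038 to 0.465. The Fisher test treats near-identical copies as independent, so these p values may be too low. In every division the fold for KCS genes lay below that over all genes. The KCS number was 8 without color break replicate 1, 7 without color break replicate 2, 10 without color break replicate 3, 8 without mature replicate 1 and 9 without mature replicate 2. In the cutin list 3 genes rose at both steps, against 0.75, and in the triterpenoid list 4 genes fell and then rose, against 3.47.

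**Figure D4:**
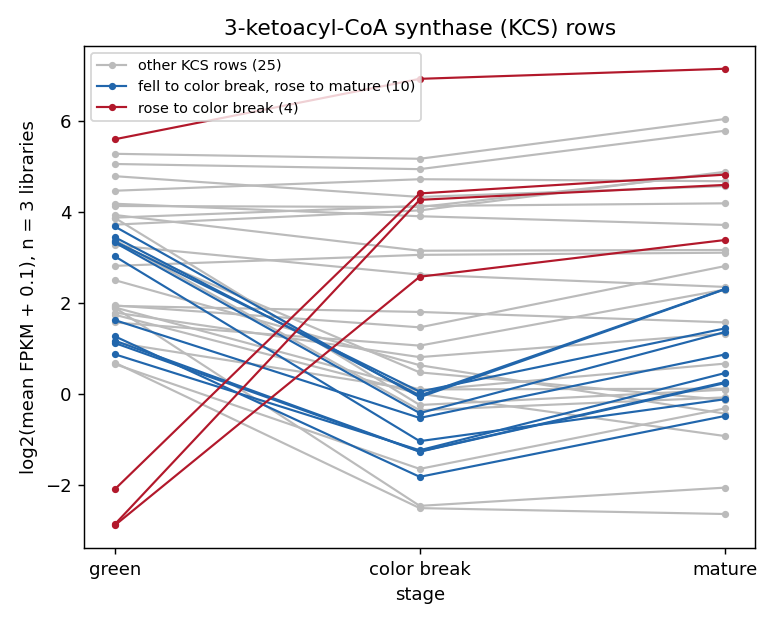
Mean expression of the 39 tested KCS genes at each stage, as log2 of the mean FPKM plus 0.1, with 1 line per gene. The 10 genes that fell to color break and then rose are blue, the 4 that rose to color break are red and the other 25 are grey.

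The comparison of mature with early green fruit spans both steps. Flavonoid and anthocyanin genes had 91 rises and 12 falls (median 3.87, camera adjusted p = 5.6e-22, and adjusted p = 0.0966 with an estimated correlation), and ANS genes summed to 8.72 ± 0.358 FPKM in green and 1545 ± 169 in mature fruit. KCS genes were split, with 7 rises and 13 falls of 39, while triterpenoid genes had 8 rises and 22 falls of 45 (median -1.13, adjusted p = 0.0216, and adjusted p = 0.208 with an estimated correlation). In total 11824 genes (24.6%) were called in edgeR, 4561 rising and 7263 falling, but with at least 5 FPKM in the higher of the 2 stages, a filter chosen after the data were seen, 2891 rose and 2627 fell at the same scaling.

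The 4 KCS genes named as rising to color break stayed high in mature fruit, with VaccDscaff24-augustus-gene-329.18 up by 1.81 ± 0.13 (adjusted p = 3.8e-06) and VaccDscaff20-augustus-gene-127.40 by 9.45 ± 0.45 (adjusted p = 5.9e-07) on the log2 scale. The neighbouring gene VaccDscaff20-processed-gene-127.33 was at least 395-fold higher than in green fruit. The CER1 gene was up by 1.18 ± 0.08 (adjusted p = 8.8e-07), with the call lost in the same alternatives as at color break, and the GPAT gene VaccDscaff27-augustus-gene-30.24 by 2.75 ± 0.16 (adjusted p = 5.2e-07). The triterpene cyclase gene VaccDscaff23-snap-gene-86.25 went from 8.93 ± 2.24 FPKM to no counts, at least 509-fold lower. The wax elongation list had 8 rises and 13 falls (0.911), wax modification 1 and 1, and cutin 3 and 6 (median -1.40 with camera pointing up, 0.647). Among GO-based lists, wax biosynthesis had 14 rises and 26 falls (0.767), cutin 5 and 8 (0.867), and triterpenoids 8 and 13 (0.289). Median and mean differed in sign for chlorophyll breakdown (0.05 and -0.66) and for the GO-based wax (-0.22 and 0.05), cutin (0.10 and -0.11) and suberin lists (0.12 and -0.14). In fry the wax elongation, seed tissue and GO-based wax, cuticle hydrocarbon and triterpenoid lists pointed up where camera pointed down.

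Of 45 photosynthesis genes 24 fell and 0 rose (adjusted p = 5.3e-12, and adjusted p = 0.0680 with an estimated correlation). Sugar genes had 12 rises and 6 falls (median 0.57 and mean -0.45, adjusted p = 2.0e-04, and adjusted p = 0.0666 with an estimated correlation). Organic acid genes had 34 rises and 5 falls (adjusted p = 3.0e-05, and adjusted p = 0.0680 with an estimated correlation). Of 35 lignin pathway genes 21 rose (adjusted p = 6.1e-11, and adjusted p = 0.0680 with an estimated correlation). Defence genes had 21 rises and 5 falls (adjusted p = 0.0216, and adjusted p = 0.208 with an estimated correlation), and cell cycle genes 5 falls (adjusted p = 0.0216, and adjusted p = 0.124 with an estimated correlation). Nutrient reservoir genes had 4 rises and 66 falls (median -7.72, or -7.45 with genes at 0 at their bound, adjusted p = 1.0e-13, and adjusted p = 0.114 with an estimated correlation). Adjusted over the list alone, the flavonoid list had 13 falls, cell wall softening 65 in place of 63, and seed tissue 11 in place of 9, and the other fixed lists had the same counts. With copies summed the triterpenoid (adjusted p = 0.280), cell cycle (0.264) and defence (0.288) calls ended. The triterpenoid call also ended with a pseudocount of 0.1 (0.154) and library size only (0.218), the cell cycle call with quantile scaling (0.170), a pseudocount of 0.1 (0.0595) and library size only (0.0555), and the defence call with quantile scaling (0.0586).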

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

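The alternatives with library-size-only scaling, a mean FPKM filter and a highest-stage FPKM filter at the scaling of the main fit, edgeR without robust fit, seed storage genes left out and limma on log2(FPKM + 1) were chosen after the data were seen, and the others before. Of 24 called results of the fixed lists, in 384 comparisons with alternatives, 327 kept their call and direction, 57 lost the call and 0 reversed. Among these the cutin and sugar lists of mature against color break held everywhere, with adjusted p up to 0.0433 and 0.0395. The GO-based lists were set only against an estimated correlation and fry. For the other called fixed lists the highest adjusted p over the alternatives lay between 0.0554 and 0.709. For 165 results of called named genes, in 4193 comparisons with alternatives, 3897 kept call and direction, 294 lost the call and 2 reversed. Of the losses 91 came from leaving out a library, in 22 of the 165 results.

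The calls for color break against green, mature against color break, mature against green and the F test numbered 10979, 661, 11824 and 28360. Without a fold threshold the first 3 were 25962, 2930 and 27494, since all genes past the adjusted p count. With a mean FPKM of at least 5 they were 3488, 196, 3776 and 12993 with TMM factors recomputed on the 18726 genes kept, and 3732, 192, 4017 and 13613 with the scaling of the main fit, so the lower numbers remain when the filter alone changes. With at least 5 FPKM in the highest of the stages compared they were 5085, 240, 5518 and 16403 at that scaling. With copies summed they were 5348, 423, 5699 and 15404 over 21729 tested descriptions, with 12 called results of the fixed lists. In limma on log2(FPKM + 1), which changes both model and scaling, the 3 comparisons gave 7734, 246 and 8187. Against these, limma on quantile scaled FPKM gave 6607, 225 and 7094, and for mature against color break limma gave 390 with a pseudocount of 0.5, 377 with TPM and 249 without trend or robust fit. Mature against color break also moved to 346 with only the 2 stages and 1036 with DESeq2. The cause was not tested for these. With an estimated correlation 2 of the 24 results of the fixed lists were called. The replicate numbers were not taken as pairs, since 2 of 9 same-number correlations of deviations from the stage mean passed 0.1. They ranged from -0.0302 to 0.223, against -0.174 to 0.117 for different numbers. Between color break and mature libraries the same-number values were all positive (0.0429, 0.105 and 0.223), so a link between these libraries is left open. With a replicate block the calls were 11144, 489, 11916 and 27280.

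Leaving out 1 library gave 10523 to 11673, 415 to 1050, 11406 to 12080 and 24640 to 29207 calls. For mature against color break the count was 1050 without color break replicate 3, with 545 of the 661 genes shared, and 415 without mature replicate 3, with 342 shared. The cause was not tested.

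The share of rises among called genes, 38.9% for color break against green, was 38.8% with median-of-ratios scaling and 23.7% with library size only. In limma it was 29.1% on log2(FPKM + 1), 45.1% with quantile scaling, 26.3% with TPM, and 24.3% and 26.1% with pseudocounts of 0.1 and 0.5. The mean FPKM filter gave 51.0%, or 66.6% at the scaling of the main fit, but a mean over 9 libraries, 6 of them not green, keeps rises more readily than falls. The highest-stage filter, which treats both alike, gave 54.0%, and no fold threshold 50.01%. For mature against green it was 38.6%, 23.9% with library size only, 48.4% with the mean FPKM filter, 64.0% with it at the scaling of the main fit, 52.4% with the highest-stage filter and 49.8% without a fold threshold. Mature against color break gave 55.5%, 61.4% with limma on log2(FPKM + 1), 66.0% with limma on TPM and 45.1% without a fold threshold. The median log2 change of color break against green shifted by -0.29 with library size only, -0.23 with limma on log2(FPKM + 1), and -0.25 with the mean FPKM filter and its own TMM factors.

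With copies summed, the gene VaccDscaff34-augustus-gene-70.30 (color break against green) changed to -0.091 and VaccDscaff43-snap-gene-245.31 (mature against green) to -0.042 on the log2 scale, with the cause not tested. Depth limits genes near 0, as the floor of 3 counts per library sets what can be seen.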

Other observations

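Tests of green RNA in color break replicate 3, a swap of that library, a mature sample under its label, more seed RNA in it, and a smaller share of cuticle-forming cells, and the filter on the higher stage, were chosen only after the result was seen. The test with different color break libraries for the fall and the rise was also added then, with its prediction written before it was run. Of 1525 GO terms with 20 to 500 tested genes, 407, 169 and 400 passed camera at the preset correlation for color break against green, mature against color break and mature against green, and 0 with an estimated correlation. The terms named here were chosen after their values were seen. From green to color break, aromatic amino acid synthesis, the route from the shikimate pathway to phenylalanine, had 36 rises and 1 fall among 57 genes (median 1.52), and chorismate biosynthesis 33 rises and 1 fall among 48. Diterpenoid synthesis had 17 rises and 2 falls among 21 genes (median 5.94), and glycolysis 35 rises and 5 falls among 164. Falls outnumbered rises in chlorophyll biosynthesis (37 of 115 genes, 0 rises), plastid translation (19 of 43, 0 rises), auxin biosynthesis (19 of 31, 0 rises) and ADP binding (111 falls and 12 rises among 330), a term that includes many disease resistance receptors.

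From color break to mature fruit the proteasome complex lay up as a set of 147 genes (median 0.21, preset camera adjusted p = 1.6e-08, with adjusted p = 0.323 with an estimated correlation), though 0 of its genes were called. Fatty acid elongase activity had 13 rises and 2 falls among 52 genes, and ferrous iron binding 0 rises and 9 falls among 32. Among storage genes, VaccDscaff43-augustus-gene-40.55, chosen after its values were seen, went from 2466 ± 223 FPKM in green fruit to 20.8 ± 26.1 at color break and 9.80 ± 9.19 in mature fruit (n = 3).

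Color break replicate 3 stood apart from color break replicates 1 and 2. Green fruit RNA mixed into it is argued against as the source of the level of the other green-specific genes. These kept 11.8% of their green level and storage genes 0.477%, a 24.7-fold difference, where mixing would give 1 common share. Storage genes also lay lower in color break replicates 1 (0.0599% against 0.711%) and 2 (0.0998% against 1.15%). The test therefore leaves a small admixture in replicate 3 open. More seed RNA in it may account for part of the gap. The 68 seed genes that fell were 3.59-fold above replicates 1 and 2 (quartiles 1.00 to 7.34). This cannot be told apart from other causes, because the quartiles reach those of photosynthesis genes (0.981 to 1.14). The gap was also not limited to storage genes, since the other green-specific genes lay above replicates 1 and 2 as well. In mature fruit those other genes kept 6.70% of their green level in replicate 3, against 2.72% and 1.89% in replicates 1 and 2. A swap with a mature library cannot be told apart from a true color break library, because on the axis from color break to mature the lowest mature library sat at 0.562 and replicate 3 at 0.659. A mature sample under its label cannot be told apart either, since its correlations with color break replicates 1 and 2 (0.939 and 0.944) lay below its highest with a mature library, 0.948, which in turn lay below the lowest among mature libraries (0.955), and a berry lot that ripened further was not tested.

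More genes fell than rose from green to color break. Without the storage genes 6651 fell and 4264 rose, against 6705 and 4274 with them, so these genes themselves make up little of the excess. Whether storage transcripts filling the green libraries bent the scaling was not decided. TMM trims extreme genes, and the median log2 change moved by only -0.00086 without them. For the scaling between libraries, the lowest ratio of falls to rises under median-of-ratios (edgeR), quantile and TPM scaling (both limma) was 1.22. These moved the median log2 change by -0.0019, 0.015 and -0.25 from the main fit. None of them moved it far toward rises, so they do not decide whether the scaling is the source. Among genes with at least 5 FPKM in the higher of the 2 stages, however, 2746 rose and 2339 fell at the scaling of the main fit, so the excess of falls lay among genes below that level in both stages. The reason was not tested.

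Of the KCS genes 10 fell to color break and then rose. Color break replicate 3 alone is argued against, since without it 10 of the 10 genes still did so. Reads moving between near-identical copies are argued against, since 4 of the 5 summed descriptions that hold these genes did so too. A smaller share of cuticle-forming cells at color break cannot be told apart from regulation of these genes, since the 9 of 80 wax and cutin genes that rose (11.25%) are near the share among all genes tested (8.89%). Noise in the color break libraries that both steps share cannot be told apart either. In a test added after the pattern was seen, with different color break libraries for the fall and the rise, the number of KCS genes doing both passed that for independent steps in each of 6 divisions, but with Fisher p up to 0.465. In every division the fold over independent steps was smaller for KCS genes than over all genes. Stage, which the design names, may be the source, as a hypothesis found and tested on the same data, with the share of cuticle-forming cells and the shared color break libraries still open.

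The 6 libraries of a comparison split into groups of 3 in 10 ways, the real one included, which are too few for a share under 0.05. The real value (fit on those 6 libraries) and the highest of the others were 10923 and 0 for color break against green, 346 and 2 for mature against color break, and 12034 and 0 for mature against green, and in each 1 split reached the real value. For the F test 1 of 100 splits drawn from 280 of the 9 libraries, the real one, gave as many genes, 28360 against at most 9. A random grouping is thus unlikely as the source. Green fruit lay far from the other stages, so the test does not separate a difference among all 3 stages from green against the rest.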
